A study of Homo sapiens with 18 samples.

How the data were processed

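ChIP-seq libraries of the transcription factors STAT3 and GR (the glucocorticoid receptor) from 9 human breast cancer cell lines were analysed. Per the series design, 5 lines are triple-negative (TNBC: HCC1187, HCC1937, HCC70, MDA-MB-231 and SUM159) and 4 are luminal (BT474, MCF-7, MDA-MB-361 and MDA-MB-453). Per the labels, STAT3 was precipitated with antibody sc-482 after ethanol and GR with antibody sc-1003 after 100 nM dexamethasone, a synthetic GR agonist, with 1 h of induction for both. Antibody and treatment therefore change together in every comparison of GR with STAT3. Each line gave 1 library per factor, so a cell line served as 1 replicate of its subtype, and no line had a second library of the same factor. The groups were STAT3 in TNBC (n = 5), STAT3 in luminal lines (n = 4), GR in TNBC (n = 5) and GR in luminal lines (n = 4). Growth media differed between lines per the labels' protocols, and the SUM159 medium held hydrocortisone, itself a GR agonist, at 1 µg per ml.

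The authors deposited a table of read counts at 126061 sites with 1 column per library, and all 18 columns were used. Per the submitters' processing notes, Bowtie and MACS2 were used with the hg19 genome. Their versions, the merging of peaks into shared sites, the handling of duplicate reads and the use of input controls in peak calling are not given in the sources used here. The deposited values were whole numbers with different totals per library, and were taken as raw counts. Sites were 100 to 550 bp wide with a median of 100 bp, and 0 sites overlapped the next.

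No gene annotation of hg19 was used here, and the gene table at hand has coordinates of another assembly. Sites are therefore given by chromosome, start and end in hg19, without gene, exon or intron. Lists of genes fixed before the data were examined could not be tied to sites and were not run.

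Tests were made in R 4.3.3. Sites were kept with the filterByExpr function of edgeR 4.0.16 (count minimum 10, total minimum 15, with the compared groups given), library sizes were totals over every site, and composition was scaled with TMM factors. Differences were tested with edgeR's quasi-likelihood test (glmQLFit with robust estimation, glmQLFTest) and Benjamini-Hochberg adjustment over the sites tested, with a threshold of 0.05. The SE of a log2 fold change was its size divided by the square root of the F statistic. STAT3 in TNBC against luminal lines and GR in TNBC against luminal lines were fitted on the 9 libraries of each factor. GR against STAT3 was fitted within TNBC and within luminal lines, and the difference between the subtype effects of the factors (the interaction) on all 18 libraries. Values per library are CPM (counts scaled to library size) computed with the same factors, and log2 CPM used a prior count of 2. A fold against a group with 1 to 3 counts in all is given as the ratio of pooled CPM with its exact 95% Poisson interval, which covers counting error only. P-values of the subtype fits measure the spread between cell lines. For GR against STAT3 and the interaction, fits without a block take the libraries of a line as independent. Differences between lines then stay in the error, and fewer sites can pass. The common dispersion (fitted spread beyond counting error) was 0.829 in TNBC, 0.431 in luminal lines and 0.797 for the interaction. With cell line as a block it was 0.0965, 0.116 and 0.121. P-values of blocked fits measure the spread left after the mean of each line is removed.

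The same lines gave the GR and the STAT3 libraries, so lines pair the libraries. As a check, GR and STAT3 deviations from their group means correlated in each of the 9 lines, with r from 0.326 to 0.849. A fit with cell line as a block was listed in advance as the alternative for GR against STAT3 and for the interaction, and its values stand beside those results. Within-line similarity was tested by an exact one-sided permutation of the pairing of lines within subtype (2880 pairings). Totals were compared with an exact two-sided permutation test over the 126 splits of 9 libraries. Chromosomes were tested as sets of sites with camera (limma 3.58.1) at a preset inter-site correlation of 0.01 and again with an estimated correlation, with adjustment over chromosomes.

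Named sites were fixed by a rule before the data were examined. For each subtype comparison and for GR against STAT3 in TNBC, sites past the adjusted threshold, with groups that did not overlap in log2 CPM and a mean log2 CPM above the median of the tested sites, were ranked by the size of the log2 fold change. The first 10 in each direction were taken, and the first 5 are given individually. For the interaction, the 5 sites of lowest p in each direction in the fit without the block were taken.

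The fits without the block were tested on simulated counts with 200 changed sites per comparison. Counts were drawn from the mean counts of the real sites and the fitted dispersion trend, with no pairing of libraries by line. Fewer sites changed than were called in the real subtype comparisons, so the shares below describe that setting. The blocked fits were not simulated. For STAT3 in TNBC against luminal lines (23054 sites), 4.48% of sites changed 4-fold, 85.1% of those changed 16-fold and 100% of those changed 64-fold were called. For GR (25277 sites) these shares were 2.99%, 23.9% and 80.3%. For GR against STAT3 they were 2.99%, 46.3% and 93.9% in TNBC (25497 sites), and 5.97%, 86.6% and 100% in luminal lines (19209 sites). For the interaction (51378 sites) they were 0%, 2.99% and 31.8%. Unchanged sites called were 2, 4, 1, 1 and 0 in the same order.

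Alternatives were DESeq2 size factors and total counts as scaling, no filter, the DESeq2 1.42.0 Wald test, autosomes alone, all 18 libraries in 1 fit, the cell-line block, other prior counts, offsets for regional copy number in 5 Mb windows, and leaving out each line. Offsets from untested sites (windows with at least 50 such sites, counts capped at 10 per site), thinning of libraries to the smallest total, and combinations of the block with these were added after seeing the data. Untested here means not tested in the fit at hand. In the STAT3 fit these sites thus included sites tested for GR, and the reverse held in the GR fit. For values over all 18 libraries, they were the sites outside the 51378 kept there. Scaling by total counts in place of TMM moved the median log2 fold change of all sites from -0.01 to -0.25 for STAT3 and from 0.10 to -0.09 for GR. For GR against STAT3 it moved from 0.15 to -0.38 in TNBC (0.08 to -0.44 with the block) and from 0.01 to -0.35 in luminal lines (-0.01 to -0.38 with the block). With DESeq2 size factors it was 0.30 in TNBC. For the interaction it moved from 0.10 to -0.03 (0.06 to -0.05 with the block). Regions of neighbouring called sites, merged within 50 kb, were also defined after seeing the data.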

Results

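STAT3 and GR occupancy was measured by ChIP-seq in 5 TNBC and 4 luminal breast cancer cell lines, with 1 library per line and factor. TNBC lines lack oestrogen and progesterone receptors and HER2 amplification. Luminal lines express genes of the luminal cells of the mammary duct. STAT3 is a transcription factor activated by cytokines, and GR is the nuclear receptor that dexamethasone activates. Counts over the 126061 shared sites totalled 451865 to 1150801 per library for STAT3 in luminal lines (n = 4) and 905624 to 1769214 for STAT3 in TNBC (n = 5). They totalled 275778 to 1337189 for GR in luminal lines (n = 4) and 829934 to 2905122 for GR in TNBC (n = 5). The GR library of BT474 was the smallest and had 35.2% of sites at 0, against 14.6% to 16.5% in the other luminal GR libraries. The mean log2 total was higher in TNBC by 0.59 for STAT3 (exact two-sided permutation p = 0.111, 126 splits) and by 1.21 for GR (exact p = 0.0714). Neither difference passed the threshold, though STAT3 did without MCF-7 (0.77, exact p = 0.0357) and GR without HCC70 (1.46, exact p = 0.0286). The site with the most counts, on chromosome 1 at 121485197 to 121485332, took 0.0686% to 0.727% of the counts of a library.

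The first comparison asked where STAT3 binding differed between TNBC and luminal lines in the absence of dexamethasone. Of 23054 sites tested, 1931 had more STAT3 signal in TNBC and 1308 had more in luminal lines, with median log2 fold changes of 3.17 and -3.23. The largest difference toward TNBC that met the naming rule was on chromosome 19 at 45091189 to 45091326, with 138 ± 58.1 CPM in TNBC (SD, n = 5) and 0.969 ± 1.94 CPM in luminal lines (SD, n = 4; log2 fold change 6.87 ± 1.11 SE, adjusted p = 0.00692). The next was on chromosome 1 at 159047055 to 159047168 (229 ± 222 CPM in TNBC against 1.75 ± 1.57 in luminal lines). A pair lay on chromosome 11 at 114165604 to 114165792 (141 ± 97.9 against 1.18 ± 1.84 CPM) and at 114178416 to 114178542. Another was on chromosome 3 at 190251525 to 190251676 (103 ± 43.8 against 0.939 ± 1.37 CPM). The chromosome 11 site starting at 114178416 had 3 counts in all luminal libraries and a TNBC to luminal ratio of 91.5 (95% interval 31.1 to 445). At the chromosome 11 site starting at 114165604, HCC1187 had 4.90 CPM where the other TNBC lines had 97.8 to 244 CPM. All 4 luminal counts at the chromosome 19 site were in BT474 (3.88 CPM). Without that line its fitted log2 fold change was 10.16, with no luminal count behind it, and the value rose from 6.63 to 8.21 at the chromosome 11 site starting at 114165604 and from 6.47 to 7.76 on chromosome 3.

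Among sites that met the naming rule, the largest STAT3 difference toward luminal lines was on chromosome 17 at 37859737 to 37859936, where luminal lines had 218 ± 195 CPM (SD, n = 4) and TNBC lines 2.45 ± 1.63 CPM (SD, n = 5; log2 fold change -6.36 ± 1.03 SE, adjusted p = 0.00692). MCF-7 had 13.6 CPM there, against 482 CPM in BT474, 214 in MDA-MB-361 and 165 in MDA-MB-453. GR signal at this site was likewise 469 CPM in BT474 and 18.2 CPM in MCF-7. Copy number at the site was not measured, so more DNA of the site in some luminal lines stays open as a source. The second site was on chromosome 14 at 95741332 to 95741569 (157 ± 119 CPM in luminal lines against 2.30 ± 1.70 in TNBC). Next were chromosome 20 at 52701660 to 52701797 (127 ± 115 against 2.73 ± 3.03 CPM) and chromosome 17 at 59434122 to 59434262 (306 ± 400 against 6.94 ± 8.68 CPM). The fifth, on chromosome 3 at 129225309 to 129225588, had 87.1 ± 42.6 CPM in luminal lines and 2.05 ± 0.631 CPM in TNBC (adjusted p = 0.00603). Without MCF-7, the chromosome 17 site starting at 59434122 lost its call (log2 fold change -5.44 with all lines and -3.97 without, adjusted p = 0.0515). Without BT474, the log2 fold change was -5.61 at the chromosome 17 site starting at 37859737 and moved from -5.52 to -4.90 on chromosome 20. Without MDA-MB-453 it moved from -6.07 to -5.44 on chromosome 14. Offsets for 5 Mb windows from tested sites moved the values furthest, to -4.26 on chromosome 14, -4.46 on chromosome 20 and -3.87 at the chromosome 17 site starting at 59434122. At the one starting at 37859737 they gave -5.58, and thinning gave -5.56. Values grew to -6.32 on chromosome 20 without HCC1937 and to -6.43 at the site starting at 59434122 without SUM159. The calls held in these fits, except without MCF-7.

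These STAT3 calls came from edgeR's quasi-likelihood test, and 6765 sites had an unadjusted p under 0.05. Scaling by total counts lowered the median log2 fold change of all sites from -0.01 to -0.25. It gave 1375 sites higher in TNBC and 1427 higher in luminal lines. Leaving out 1 luminal line lowered the calls to 1199 without MDA-MB-453 (527 higher in TNBC, 672 in luminal lines), 1437 without MDA-MB-361 (663 and 774) and 1750 without BT474. With no filter on low counts, 884 sites were higher in TNBC and 1392 in luminal lines, and 1220 of the 3239 sites were among them.

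**Figure D1:**
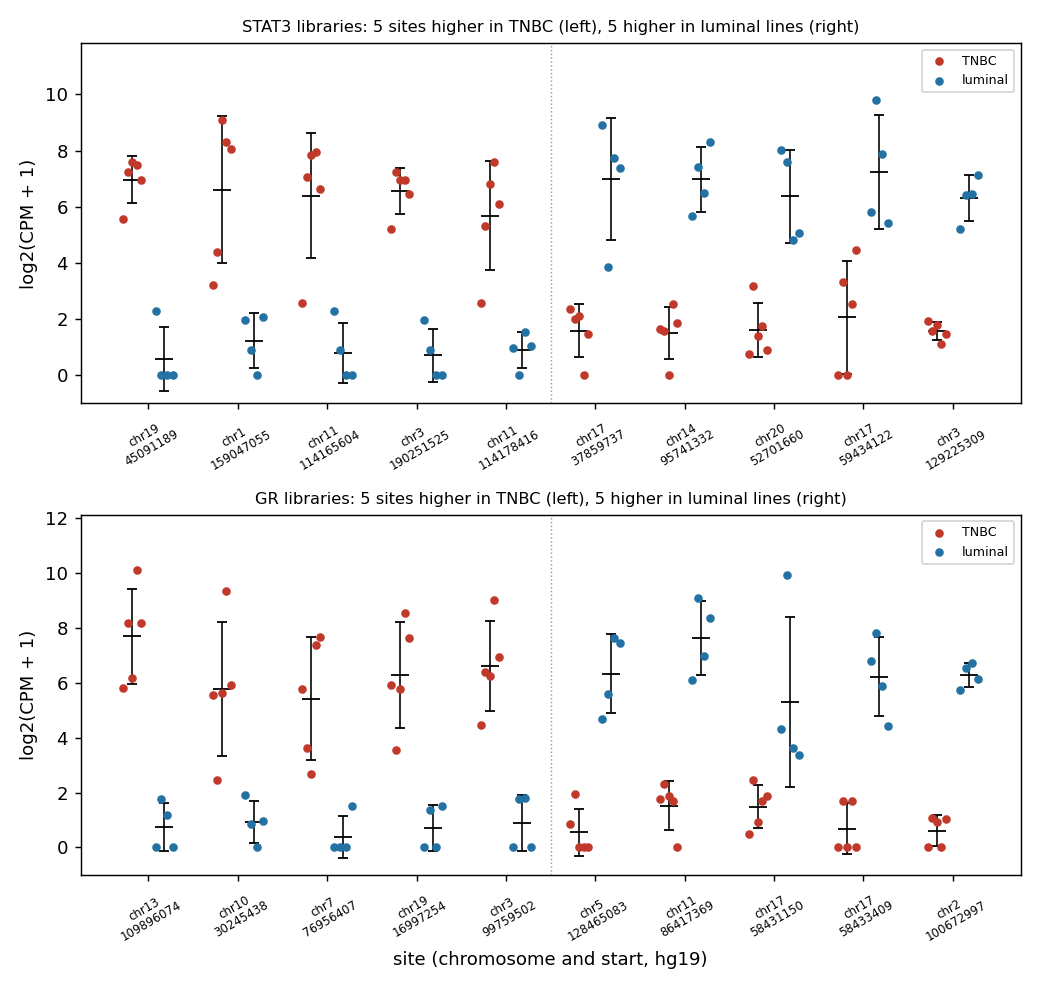
Each point is 1 library, as log2(CPM + 1) on the vertical axis, at the 5 leading sites per direction (horizontal axis, chromosome and hg19 start) for STAT3 (top) and GR (bottom), with TNBC in red and luminal lines in blue; black bars are the mean ± SD over 5 TNBC or 4 luminal lines. The naming rule took only sites where the groups do not overlap. At the chromosome 17 site starting at 58431150 the GR library of MCF-7 stands at 964 CPM above 9.38 to 19.0 CPM in the other luminal lines.

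The same question was asked of GR after dexamethasone. GR signal was higher in TNBC at 1492 and higher in luminal lines at 1873 of 25277 sites tested, with median log2 fold changes of 4.13 and -3.97. The leading TNBC site under the naming rule was on chromosome 13 at 109896074 to 109896287, with 357 ± 421 CPM in TNBC (SD, n = 5) and 0.906 ± 1.14 CPM in luminal lines (SD, n = 4; log2 fold change 8.30 ± 1.56 SE, adjusted p = 0.00629). Next came chromosome 10 at 30245438 to 30245622, with a ratio of 125 (95% interval 42.7 to 608) over 3 luminal counts. There MDA-MB-231 had 653 CPM and the other TNBC lines 4.52 to 58.7 CPM. On chromosome 7 at 76956407 to 76956522 the ratio was 148 (95% interval 40.7 to 1222) over 2 luminal counts. The sites on chromosome 19 at 16997254 to 16997402 and on chromosome 3 at 99759502 to 99759620 had 139 ± 149 and 162 ± 198 CPM in TNBC, against 0.864 ± 1.00 and 1.22 ± 1.41 CPM in luminal lines. Without MDA-MB-231, the log2 fold change fell to 7.30 on chromosome 13, from 7.30 to 5.30 on chromosome 10, from 6.96 to 6.19 on chromosome 19 and from 6.81 to 5.73 on chromosome 3. Without SUM159 it fell from 7.09 to 6.42 on chromosome 7. Thinning to the smallest total gave 5.81 on chromosome 7, 5.49 on chromosome 10, 7.89 on chromosome 19 and 9.30 on chromosome 13. Window offsets gave 6.15 (from tested sites) on chromosome 10 and 6.23 (from untested sites) on chromosome 3. Both luminal counts on chromosome 7 were in MDA-MB-453, without which the fitted value was 9.87 with no luminal count behind it, and without MCF-7 the value on chromosome 13 was 9.28. All 5 sites kept their calls in these fits.

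Among sites that met the naming rule, GR differed most toward luminal lines on chromosome 5 at 128465083 to 128465192 (110 ± 86.2 CPM in luminal lines against 0.723 ± 1.22 in TNBC; log2 fold change -6.96 ± 1.32 SE, adjusted p = 0.00629) and on chromosome 11 at 86417369 to 86417694 (266 ± 217 against 2.24 ± 1.43 CPM). A pair of sites on chromosome 17, at 58431150 to 58431249 and at 58433409 to 58433508, had 251 ± 475 and 102 ± 87.2 CPM in luminal lines and 2.13 ± 1.62 and 0.891 ± 1.22 CPM in TNBC. The first of them rested on MCF-7, and without that line its log2 fold change was -2.53 with an adjusted p of 0.0903. Without MCF-7, the log2 fold change also moved from -6.79 to -6.03 at the second and from -6.84 to -6.20 on chromosome 11, both still called. The fifth site, on chromosome 2 at 100672997 to 100673175, had little spread among luminal lines (78.8 ± 23.2 CPM, against 0.618 ± 0.571 in TNBC). Thinning moved the log2 fold change to -4.88 on chromosome 5, -5.90 on chromosome 11, -5.96 at the second chromosome 17 site and from -6.77 to -6.08 on chromosome 2. Window offsets from tested sites gave -4.47 and -5.07 at the chromosome 17 sites and -6.18 on chromosome 11, and without HCC1937 the values were -8.23 on chromosome 5 and -7.66 at the second chromosome 17 site, all still called.

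Which direction held more GR sites depended on the fit, with 947 higher in TNBC and 1739 in luminal lines under total-count scaling, 2768 and 2299 with all 18 libraries in 1 fit, and 3870 and 2934 in DESeq2. GR calls fell to 1245 without MDA-MB-453, 1339 without MDA-MB-361, 1673 without BT474 and 1946 without MCF-7, and in these 4 fits the sites higher in TNBC numbered 163, 195, 302 and 629. With no filter on low counts, 0 sites passed in edgeR, the named sites included, although 26156 had an unadjusted p under 0.05 and DESeq2 called 6804 of the filtered sites.

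Whether the factors differed between subtypes at the same places was asked over the 14412 sites tested for both. The TNBC over luminal log2 fold changes of STAT3 and GR correlated across sites (Pearson r = 0.859, Spearman rho = 0.839; jackknife SE of r over lines 0.033), and 81.9% of sites had the same sign. Both factors were higher in TNBC at 378 sites, where independent lists would share 41.7, and both were higher in luminal lines at 516 sites, where independent lists would share 40.1. No site was higher in TNBC for 1 factor and higher in luminal lines for the other, where independent lists would give 46.7 and 35.8. Of 1996 sites called for STAT3 that were also tested for GR, 99.1% had the same sign for GR, with median GR log2 fold changes of 2.71 at sites higher and -3.23 at sites lower in TNBC. Of 1186 sites called for GR that were also tested for STAT3, 99.8% had the same sign for STAT3. The called sites numbered 3239 for STAT3 and 3365 for GR. Those not tested for the other factor stand outside these values. Sites are not independent replicates, and the libraries of both factors came from the same 9 lines, so the sharing describes these lines.

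**Figure D2:**
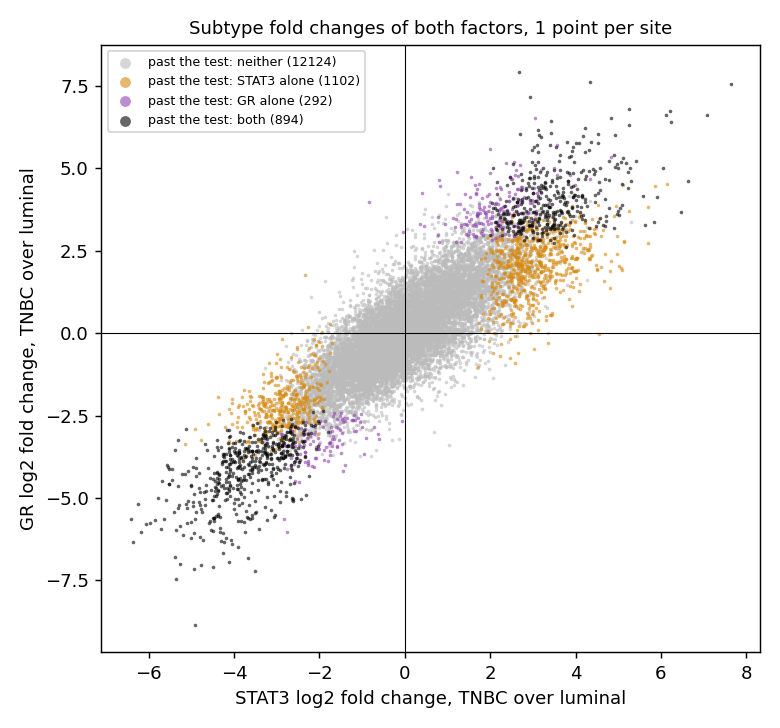
Each point is 1 of the 14412 sites tested for both factors, with the STAT3 log2 fold change of TNBC over luminal lines on the horizontal axis and that of GR on the vertical axis, coloured by which factor passed the adjusted threshold. Sites past it for both (black) lie in the upper right (378) and lower left (516) and none in the other quadrants.

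Within TNBC, GR after dexamethasone was compared with STAT3 after ethanol to find sites where 1 factor exceeded the other. The top 1% of sites held 17.2% to 30.3% of the counts of GR libraries and 13.7% to 18.8% of those of STAT3 libraries. The share was higher for GR in every line, so the counts and folds below also reflect how strongly each library was enriched, and not occupancy alone. GR exceeded STAT3 at 1003 and STAT3 exceeded GR at 552 of 25497 sites. Among sites that met the naming rule, the largest excess of GR was on chromosome 3 at 127023210 to 127023353, with 932 ± 722 CPM for GR and 2.73 ± 2.94 CPM for STAT3 (SD, n = 5 each; log2 fold change 8.38 ± 1.15 SE, adjusted p = 0.00869). It was followed by chromosome 18 at 55953065 to 55953213 (ratio 228, 95% interval 77.7 to 1108, over 3 STAT3 counts) and chromosome 6 at 35690383 to 35690522 (331 ± 486 CPM for GR against 1.52 ± 1.67 for STAT3). Next were chromosome 8 at 91013914 to 91014111 (822 ± 989 against 4.19 ± 2.60 CPM) and chromosome 2 at 223317258 to 223317450 (160 ± 187 against 0.825 ± 0.961 CPM). Under the same rule, STAT3 exceeded GR most on chromosome 7 at 130756934 to 130757073 (165 ± 113 CPM for STAT3 against 2.12 ± 1.11 for GR; log2 fold change -6.21 ± 0.94 SE, adjusted p = 0.00869) and on chromosome 17 at 80408712 to 80408831 (126 ± 50.5 against 2.38 ± 1.75 CPM). A pair of sites on chromosome 19, at 893250 to 893408 and at 8943391 to 8943552, had 176 ± 84.9 and 70.5 ± 29.3 CPM for STAT3 and 4.78 ± 2.59 and 1.78 ± 0.886 CPM for GR. Another lay on chromosome 7 at 32720543 to 32720667 (136 ± 128 against 3.72 ± 3.49 CPM).

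With cell line as a block, GR exceeded STAT3 at 6100 and STAT3 exceeded GR at 4929 sites in TNBC, and the 10 sites above kept their calls (highest adjusted p 8.72e-11). Without the block, 0 sites passed in edgeR when HCC1937 or HCC70 was left out, and 0 with no filter on low counts. At an unadjusted p under 0.05 there were 4011, 4117 and 13928 sites, and DESeq2 on all 10 libraries called 4279. In edgeR 595, 660 and 503 sites passed without HCC1187, MDA-MB-231 and SUM159. The site on chromosome 6 starting at 35690383 also lost its call without HCC1187 or SUM159, and that on chromosome 7 starting at 32720543 without HCC1187 or MDA-MB-231. Without MDA-MB-231, the log2 fold change fell from 8.38 to 7.74 on chromosome 3, from 7.69 to 6.72 on chromosome 6, from 7.59 to 6.43 on chromosome 8 and from 7.37 to 6.09 on chromosome 2, all 4 still called. Without SUM159 it rose to 8.19 on chromosome 2 and from 7.85 to 8.90 on chromosome 18. Total-count scaling gave 7.75, 6.96, 6.83 and 6.67 on chromosomes 3, 6, 8 and 2 and moved the chromosome 17 site from -5.70 to -6.32. Thinning gave 7.22 on chromosome 18 and moved the chromosome 19 site starting at 8943391 from -5.19 to -5.89. On chromosome 8 the block alone gave 6.58, and with total-count scaling as well 6.04. These calls held too. The split of directions turned under total-count scaling, to 745 GR-higher and 1110 STAT3-higher sites without the block and 3866 and 8419 with it. The median log2 fold change of all sites moved from 0.15 to -0.38 without the block.

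**Figure D3:**
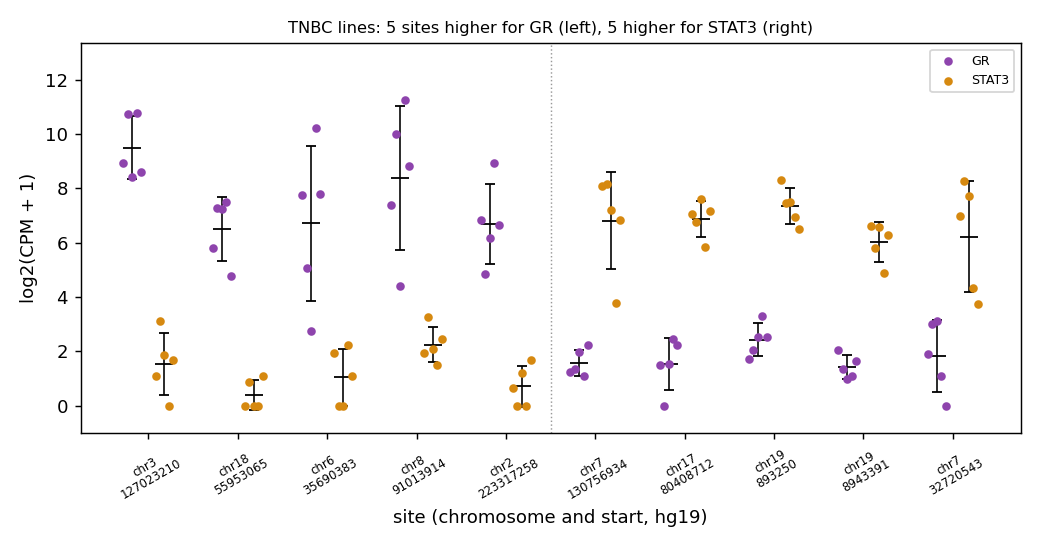
Each point is 1 TNBC library, as log2(CPM + 1) on the vertical axis, at the 5 leading sites per direction (horizontal axis, chromosome and hg19 start), with GR in purple and STAT3 in orange; black bars are the mean ± SD over 5 lines. At the chromosome 3 site the GR libraries average 932 CPM and the STAT3 libraries 2.73 CPM.

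In luminal lines, GR exceeded STAT3 at 247 and STAT3 exceeded GR at 23 of 19209 sites, with median log2 fold changes of 4.01 and -3.17. With cell line as a block these counts were 2890 and 1985. Under total-count scaling they were 139 and 32 without the block and 1941 and 3927 with it. With the block, 2243 sites passed without MDA-MB-453, 2629 without MCF-7 and 2442 after thinning. Without the block, leaving out any 1 of the 4 lines left 0 sites past the threshold in edgeR, with 2366 to 3350 sites at an unadjusted p under 0.05, while DESeq2 on all 8 libraries called 2093. All 8 libraries gave 146 sites with no filter, 97 after thinning, and 961 and 711 with window offsets from tested and untested sites. Over the 9442 sites tested in both subtypes with the block, GR exceeded STAT3 in both at 848 sites (215 if the lists were independent) and STAT3 exceeded GR in both at 753 (272). Only 4 sites went opposite ways, all with STAT3 higher in TNBC and GR higher in luminal lines, where independent lists would give 225 such sites and 259 of the opposite kind.

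Whether the subtype difference itself differed between GR and STAT3 was tested with the interaction over all 18 libraries. None of 51378 sites passed in edgeR without the block, where 1431 (2.79%) had an unadjusted p under 0.05 and DESeq2 called 20. That fit ignores the pairing by line and leaves line differences in the error, so its 0 calls do not show equal subtype effects. With cell line as a block, 460 sites passed: 266 with the higher TNBC over luminal effect for GR and 194 with the higher effect for STAT3. On chromosome 13 at 52344067 to 52344192, GR had 50.3 ± 34.8 CPM in TNBC (SD, n = 5) and 1.77 ± 2.05 CPM in luminal lines (SD, n = 4), whereas STAT3 had 1.46 ± 1.01 and 3.82 ± 0.715 CPM (difference of log2 effects 6.39 ± 0.99 SE, blocked adjusted p = 4.24e-05). On chromosome 3 at 141085372 to 141085554, GR had 225 ± 160 CPM in TNBC and 10.3 ± 3.88 CPM in luminal lines, and STAT3 had 23.7 ± 12.2 and 17.4 ± 8.60 CPM (blocked difference 3.75 ± 0.77 SE). On chromosome 9 at 130533721 to 130533847, STAT3 had 63.6 ± 31.2 CPM in TNBC and 6.86 ± 2.44 CPM in luminal lines, and GR had 1.88 ± 1.16 and 5.34 ± 4.94 CPM (blocked difference -4.44 ± 0.88 SE). On chromosome 2 at 24713686 to 24713816, STAT3 had 47.4 ± 11.5 CPM in TNBC and 4.53 ± 2.04 CPM in luminal lines, and GR had 2.60 ± 1.98 and 5.80 ± 3.12 CPM (blocked difference -4.36 ± 0.82 SE). With the block, 88 sites passed without MDA-MB-361, 108 without MDA-MB-453 and 290 without HCC1187. The split of directions turned without BT474, where 173 of 468 sites had the higher effect for GR, and narrowly without MDA-MB-231 (281 for GR and 288 for STAT3). It also turned under total-count scaling (307 with the higher effect for GR and 326 for STAT3) and after thinning to the smallest total (7 and 12). Of the 4 sites above, thinning left the one on chromosome 9 called (-6.75, adjusted p = 0.0463) and not those on chromosome 13 (6.43, adjusted p = 0.0580), chromosome 3 (3.33, adjusted p = 0.0894) and chromosome 2 (-5.11, adjusted p = 0.145).

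The design also allowed a test of whether the GR and STAT3 libraries of a line deviated together. Across 51378 sites, GR and STAT3 deviations from their subtype means correlated with a mean r of 0.640 ± 0.170 (SD, n = 9 lines; exact one-sided permutation p = 0.000347, the smallest that 2880 pairings can give). The correlation was highest in HCC1187 (0.849) and SUM159 (0.837) and lowest in BT474 (0.326), whose GR library had the lowest total. It averaged 0.755 over TNBC and 0.496 over luminal lines, a difference that was not tested. Different lines of a subtype averaged -0.177, where centring on the group mean gives values below 0, and the highest mean of any other pairing was 0.542.

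**Figure D4:**
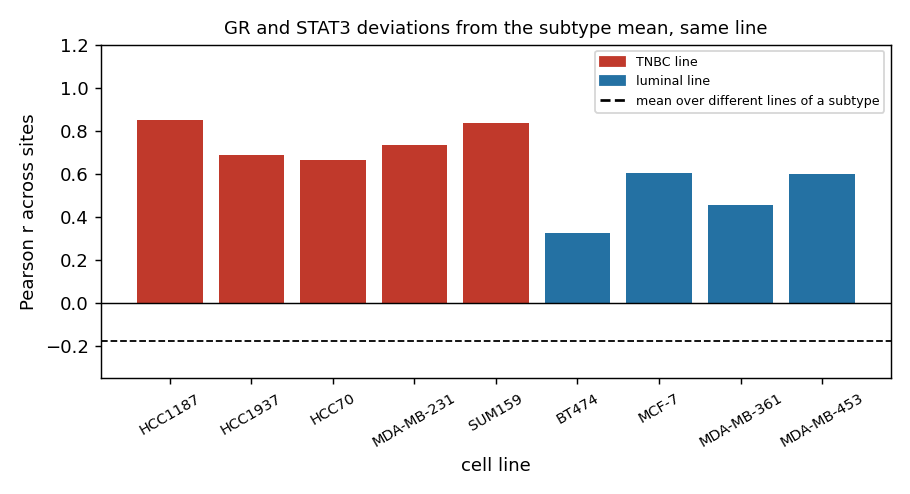
Bars show, for each cell line (horizontal axis; TNBC in red, luminal in blue), the Pearson r across sites between the deviations of its GR and its STAT3 library from the subtype means (vertical axis, no unit). All 9 bars, from 0.326 to 0.849, stand above 0. The dashed line at -0.177 is the mean over different lines of a subtype, which centring on the group mean sets below 0.

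By chromosome, STAT3 signal was lower in TNBC than in luminal lines on chromosome 17 (median log2 fold change of 1211 sites -0.66, adjusted p = 0.000714) and on chromosome 14 (935 sites, -0.52, adjusted p = 0.0173). Neither call held with an estimated correlation between sites (adjusted p = 0.753 and adjusted p = 0.859). On chromosome 17, 179 sites (14.8%) were called higher in luminal lines and 51 higher in TNBC. GR signal was also lower in TNBC on chromosome 17 (1080 sites, -0.57, adjusted p = 0.0273), with 134 sites called higher in luminal lines and 27 higher in TNBC. With an estimated correlation this call did not hold (adjusted p = 0.971). GR signal was higher in TNBC on chromosome 9 (1019 sites, 0.63, adjusted p = 0.0321), which did not hold with an estimated correlation either (adjusted p = 0.614). Leaving out 1 line ended the STAT3 call on chromosome 14 (without MCF-7, adjusted p = 0.0655). It ended both GR calls without HCC1187 (adjusted p = 0.0884) or HCC1937 (0.0519 on chromosome 17 and 0.0597 on chromosome 9), and the GR call on chromosome 9 without MDA-MB-453 (0.0751). The STAT3 call on chromosome 17 held without any 1 line (highest adjusted p 0.00732). The sign of the median differed from the direction of the test on chromosomes 8, 11 and 21 for STAT3 and on chromosomes 2, 4 and 8 for GR, none past the threshold.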

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

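The window offsets from untested sites and the correlation of fold changes under them, the thinning and the combinations of these with the cell-line block were chosen after the results were seen. So were the 60 splits of the blocked interaction, kept from a longer draw so as to include its highest other count. In 82 groups of 4 or 5 libraries checked for a library far from the others, 7 stood apart, and chance alone sets about 1 in 20 apart.

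The BT474 GR library had 35.2% of sites at 0, against 14.6% to 16.5% in the other luminal GR libraries, and 0.446% of its counts at the mitochondrial site, against 0.0726% to 0.123%. The MCF-7 STAT3 library had 18.1% of its counts in the top 1% of sites, against 14.03% to 14.4% in the other luminal STAT3 libraries. MCF-7 had 964 CPM of GR signal on chromosome 17 at 58431150 to 58431249, against 9.38 to 19.0 CPM in the other luminal lines. HCC1187 had 4.90 CPM of STAT3 signal on chromosome 11 at 114165604 to 114165792, against 97.8 to 244 CPM in the other TNBC lines. BT474 had 3.88 CPM of STAT3 signal on chromosome 19 at 45091189 to 45091326, and MDA-MB-453 had 1.88 CPM of GR signal on chromosome 7 at 76956407 to 76956522, where the other luminal lines had 0.

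The subtype effect differed between GR and STAT3 at 460 sites with the cell-line block. The named sites were ranked by p without the block, and not by blocked p. At the 5 named sites with the higher effect for GR, the blocked difference of log2 effects was 6.39 on chromosome 13 at 52344067, 6.49 on chromosome 18 at 29873220, 5.82 on chromosome 13 at 85668003, 6.03 on chromosome 1 at 160101904 and 3.75 on chromosome 3 at 141085372. At the 5 with the higher effect for STAT3 it was -4.36 on chromosome 2 at 24713686, -4.45 on chromosome 3 at 138048649, -4.92 on chromosome 19 at 54975617, -4.44 on chromosome 9 at 130533721 and -4.64 on chromosome 1 at 112162187. Over the alternatives run, with and without the block, the difference ranged from 4.10 to 6.71 on chromosome 18. It ranged from -6.91 to -4.15 on chromosome 1 at 112162187 and from -6.76 to -4.15 on chromosome 9. GR totals averaged higher in TNBC (not past the test), and depth is 1 possible source of such differences. After every library was thinned to the smallest total, 100% of the 460 sites kept their sign, their median size was 3.64 against 3.67 before, and 17 stayed past the threshold, as the median SE rose from 0.903 to 1.36 with fewer counts. The bounds set in advance, on sign and size, could hardly have been missed, because random thinning keeps the expected ratios and these sites were chosen for their effects, so depth stays open. A different response of the subtypes to dexamethasone and a different level of either factor also stay open, since no untreated GR library and no dexamethasone-treated STAT3 library was analysed here.

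The luminal excess of STAT3 on chromosome 17 was weighed against regional copy number, since more DNA of a region gives more reads in any ChIP. Without correction, the share of tested chromosome 17 sites called higher in luminal lines was 2.61 times that of all sites (95% interval over resampled 5 Mb windows 1.45 to 3.68). With offsets from sites not tested for STAT3 the ratio was 1.65 (1.04 to 2.21), with 115 sites called on the chromosome. Part of the excess thus went with the regional signal at those sites, and the test did not settle whether all of it may. Sites tested for GR were among them, so the offsets may hold GR binding as well as copy number. A single luminal line as the source was not excluded by the bound set in advance, though the lowest ratio without 1 luminal line was 2.43 (without MDA-MB-361; interval 1.26 to 3.58). A subtype difference in STAT3 binding at these sites stays open.

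The agreement between STAT3 and GR fold changes (r = 0.859) was not removed by window offsets from untested sites (r = 0.847). These offsets sum signal over whole windows with capped counts, so they address regional copy number and not changes smaller than a window. In each fit they also drew on sites tested for the other factor. Computed over all 18 libraries, such offsets could differ between the factors of a line. From 35 to 40 Mb of chromosome 17, BT474 had 0.74 for STAT3 and 1.42 for GR, though from 55 to 60 Mb MCF-7 had 1.06 and 0.99. Part of a regional change may thus remain after correction. That part and copy number changes smaller than a window stay open as sources of the agreement. The agreement did not rest on sites with low counts, as r was 0.881 over the 5738 sites above the median signal in both fits. A signal common to both antibodies in a line, such as the accessibility of the chromatin, predicted that r would stay high even where 1 factor far exceeded the other. At the 230 sites where 1 factor exceeded the other at least 4-fold in both subtypes, r was 0.810, but choosing sites where the same factor exceeded the other in both subtypes favours similar fold changes, so this value does not decide. Such a signal and joint binding of the factors stay open, because neither input nor untargeted libraries were analysed here.

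Other splits of the same libraries show whether chance can be excluded. Of 100 splits of the 9 STAT3 libraries, 1, the real one, gave as many as 3239 sites, and the highest other gave 927. For GR, 1 of 100 splits gave as many as 3365, and the highest other gave 484. For GR against STAT3 in TNBC, 1 of 100 splits reached 1555 and the highest other gave 509, while the other splits that part every pair of libraries of a line gave 0. In luminal lines, 1 of 35 splits reached 270 and the highest other gave 0. Chance is thus excluded at the level of 5% for the STAT3 and GR comparisons of subtypes. For GR against STAT3, with or without the block, only the splits that part every pair respect the pairing, 16 in TNBC and 8 in luminal lines, too few for a share under 0.05. With the block, the real one alone, 1 split in each case, gave 11029 and 4875 sites, and the highest other gave 0. For the interaction without the block, the real count was 0 and the highest other was 0, so 100 of 100 splits gave as many. Counts of 0 throughout cannot tell the real split from the others, and that fit ignores the pairing by line. With the block, 1 of 60 splits, the real one, reached 460, and the highest other gave 153. These 60 were chosen after the counts were seen, so their share is not read as a test at a set level.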

How the results depend on the processing

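Alternatives with offsets from untested sites, thinning, adjustment over the filtered sites alone, and the block combined with another choice were chosen after seeing the data. Except where a cause is named, the cause of a change was not tested. The DESeq2 Wald test gave 6082 sites for STAT3, 6804 for GR (3870 higher in TNBC), 4279 for GR against STAT3 in TNBC, 2093 in luminal lines and 20 for the interaction. Without a filter, 0 sites passed in edgeR for GR and 0 for GR against STAT3 in TNBC, with 26156 and 13928 at an unadjusted p under 0.05, and 146 passed in luminal lines. After adjustment over the filtered sites alone these were 1714, 894 and 439. All 18 libraries in 1 fit gave 5067 GR sites (2768 higher in TNBC). With cell line as a block, 11029 sites passed for GR against STAT3 in TNBC, 4875 in luminal lines and 460 for the interaction. These were 12285, 5868 and 633 with the block and total-count scaling, 10025, 2442 and 19 with the block and thinning, and 11038, 5066 and 491 with the block and offsets from untested sites. The block changed no other call, since it applies to no other comparison. For GR against STAT3 in luminal lines without the block, total-count scaling gave 171, window offsets from tested sites 961, offsets from untested sites 711 and thinning 97. Leaving out 1 line gave 1199 (without MDA-MB-453) to 3631 STAT3 sites and 1245 (without MDA-MB-453) to 4148 GR sites, with 1437 and 1339 without MDA-MB-361, 1750 and 1673 without BT474, and 1946 GR sites without MCF-7. It gave 0 (without HCC1937 or HCC70) to 660 (without MDA-MB-231) for GR against STAT3 in TNBC, 595 without HCC1187, 503 without SUM159, and 0 to 0 in luminal lines. With the block these ranges were 9258 to 10303 in TNBC, 2243 (without MDA-MB-453) to 6274 in luminal lines, with 2629 without MCF-7, and 88 (without MDA-MB-361) to 569 for the interaction, with 108 without MDA-MB-453 and 290 without HCC1187. Each of these fits had fewer libraries. The correlation of fold changes was 0.706 with no filter and 0.834 to 0.859 under other scalings and window offsets. The mean same-line correlation kept its call under every alternative run, from 0.559 with no filter to 0.688 without BT474, with 0.593 and 0.596 under window offsets. The difference in log2 totals ranged from 0.32 (without MDA-MB-361) to 0.77 for STAT3 and from 0.75 (without BT474) to 1.51 for GR. It passed the exact permutation test without MCF-7 for STAT3 (0.77, p = 0.0357) and without HCC70 for GR (1.46, p = 0.0286). With an estimated correlation, 0 chromosomes passed for STAT3 and 0 for GR. Without 1 line, 1 (MCF-7) to 5 (HCC1937 or MDA-MB-453) chromosomes passed for STAT3, with 4 without BT474, and 0 (HCC1187 or HCC1937) to 4 (HCC70) for GR, with 1 without MDA-MB-453. None of the sites given individually (5 per direction for STAT3, GR, GR against STAT3 in TNBC and the interaction) changed direction under the alternatives run. Of their alternatives, 652 kept the side of the threshold, 46 lost the call and 39 (for the interaction) gained one. An alternative that gave no adjusted p is left out of these numbers and of the check of direction. This affected the GR sites on chromosome 10 at 30245438 and chromosome 17 at 58431150 (17 counted, against 18 at the other GR sites). It also affected the interaction site on chromosome 3 at 138048649 (20, against 21). The planned gene lists were not run, with their alternatives, because no hg19 annotation was used here. Depth limits the comparisons in BT474, whose GR library had a median of 1 count per site.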

Other observations

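The regions, the windows of untested sites and the sorting of interaction sites were chosen after seeing the data. Regions merged called sites of 1 direction within 50 kb, and no test was run on them. Most called sites stood alone: 1174 of 1463 STAT3 regions higher in TNBC and 694 of 900 higher in luminal lines held 1 site, as did 921 of 1149 and 1187 of 1467 GR regions. The region with the most STAT3 sites higher in TNBC was on chromosome 7 at 55035175 to 55200785, where 11 of 14 tested sites were called (median log2 fold change 3.42) and 4 of 12 tested for GR were called the same way. On chromosome 9 at 93940196 to 93970537, 7 of 8 STAT3 sites were called (median 3.50) together with 6 of 7 GR sites. The GR region with the most sites higher in TNBC overlapped it, at 93893944 to 93970737, with 9 of 10 GR sites called (median 4.19). STAT3 regions with no GR call included chromosome 17 at 76339288 to 76380442 (8 of 11 STAT3 sites, median 3.44; 0 of 3 for GR) and chromosome 6 at 126188831 to 126269045 (7 of 10 STAT3 sites, median 3.28; 0 of 9 for GR).

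Toward luminal lines, the region with the most STAT3 sites was on chromosome 17 at 48940726 to 49027995, with 16 of 21 sites called (median log2 fold change -3.34) and 7 of 13 for GR. A second one on that chromosome, at 57914771 to 57970521, held 11 of 19 STAT3 sites (median -3.21) and 7 of 16 for GR, and another, at 37831167 to 37910560, held 6 of 10 STAT3 sites (median -3.63) and 4 of 10 for GR. On chromosome 2, 13 of 17 STAT3 sites were called at 20652392 to 20696564 (median -3.29), with 6 of 15 for GR, and all 7 tested sites were called at 237721967 to 237733715 (median -5.64), with 3 of 3 for GR. On chromosome 22 at 29180012 to 29219244, 8 of 9 STAT3 sites (median -3.87) and 6 of 8 GR sites were called.

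Signal at untested sites, summed in 593 windows of 5 Mb, correlated between the STAT3 and GR libraries of a line with r from 0.725 to 0.948. The mean between different lines was -0.112, where centring on the mean of the factor's libraries gives values below 0. In the window from 35 to 40 Mb of chromosome 17, luminal lines ranged from -0.61 (MDA-MB-361) to 0.74 (BT474) for STAT3, as log2 against the mean of the factor's libraries, and TNBC lines from -0.19 to 0.37. The GR libraries of the same luminal lines were at -0.69 and 1.42. From 55 to 60 Mb, luminal lines ranged from -0.84 (MDA-MB-453) to 1.06 (MCF-7) for STAT3 and from -0.57 to 0.99 for GR, and TNBC lines from -1.11 (HCC1187) to 0.11 (HCC1937) for STAT3. From 60 to 65 Mb, luminal lines ranged from -0.45 (BT474) to 1.11 (MDA-MB-361) for STAT3 and from -0.47 to 1.24 for GR, and TNBC lines from -0.84 (HCC1187) to 0.23 (MDA-MB-231) for STAT3. From 50 to 55 Mb of chromosome 20, luminal lines ranged from -0.77 (MDA-MB-453) to 0.96 (BT474) for STAT3 and from -0.94 to 1.88 for GR, and TNBC lines from -1.03 (HCC1187) to 0.40 (HCC1937) for STAT3.

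Of the 460 sites whose subtype effect differed between the factors with the cell-line block, 266 had the higher effect for GR. The GR comparison of subtypes tested 241 of these and called 119 higher in TNBC, and the STAT3 comparison tested 39 and called 3 higher in luminal lines. Of the 194 with the higher effect for STAT3, the STAT3 comparison tested 149 and called 94 higher in TNBC, and the GR comparison tested 50 and called 15 higher in luminal lines. The filter on low counts left the numbers tested unequal, and the sites were chosen for their difference, so the calls are not compared.

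The mean pairwise r among luminal libraries was 0.530, against 0.407 among TNBC libraries, for STAT3, and 0.471 against 0.382 for GR. Neither difference passed an exact two-sided permutation test over 126 splits (p = 0.198 and 0.373). Each of the 18 libraries had its highest correlation with a library of the other factor in that of its own line.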
